A study of Mus musculus with 10 samples.

How the data were processed

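RNA from 10 mouse samples, 5 T-C cell and 5 control cell, was profiled by a microarray service (LC Sciences). p-values measure the spread between these samples, since nothing says they came from separate animals or cultures. Per the labels, 1 µg of total RNA extracted with Trizol was extended with a poly(A) tail, ligated to an oligonucleotide tag and stained with Cy3. The series is filed under a sequencing type, but the files hold spot brightness. Per the file headers, each file gives the median spot intensity, a linear scanner brightness, which the authors deposited without scaling between arrays. A second pair of brightness columns is empty in all 10 files, and no background column was used. The scanner, image software and miRBase release are not given in the sources used here. Files of T-C cell samples are headed as treated and files of control cell samples as control. The file of T-C cell replicate 1 has 1 extra column. The headers also number the arrays, and the numbers of the groups do not interleave: those of the control cell arrays lie above that of T-C cell replicate 1 and below those of the other T-C cell arrays. What they number is not given in the sources used here, so no batch was drawn from them and no within-batch value was computed. A batch that changes both below and above the control cell numbers cannot be told apart from the group. For a steady drift or a single change, T-C cell replicate 1 is the only T-C cell array numbered below the control cell arrays. Such a drift or change was not tested, and 1 array would decide little.

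Each array held 3968 spots: 3784 miRNA spots, 16 blank spots, 148 calibration spots and 20 spots for 5S rRNA, and 13 probes stand for several mature miRNAs. Groups and replicate numbers come from the sample titles. No arrays were duplicates of each other: the highest correlation between arrays was 0.976 (control cell replicates 2 and 3, with 1 identical value among all spots) and the lowest 0.738.

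Intensities were converted to log2(intensity + 50), the 2 spots of each miRNA were averaged, and arrays were normalized by cyclic loess (limma 3.58.1 in R 4.3.3, jsonlite 2.0.0). The design had foreseen background subtraction only where a background column existed, and the added 50 is the branch for files with a single intensity column. A miRNA counted as detected where the mean of its spots exceeded the mean of the blank spots plus 3 SD, which gave limits from 64.0 to 474, and was tested if detected on at least 5 of 10 arrays. Groups were compared with limma (lmFit and eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over 476 miRNAs and a threshold of 0.05 on the adjusted p. Intervals of differences are 95% intervals from limma, and differences are T-C cell minus control cell. Numbers of detected miRNAs, raw intensities and list means were compared by exact two-sided permutation over all splits of 5 against 5, with Benjamini-Hochberg adjustment over the 13 lists with at least 3 tested members. A list mean is the mean over its tested members on each array. Camera, with a correlation preset at 0.01 or estimated, was a further test of the lists.

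The comparison, the 14 lists and the rule for named miRNAs were set before the data were examined. Where more than 24 miRNAs passed, the rule named the 10 largest increases and the 10 largest decreases among those whose groups did not overlap, which gave 5 and 8. It also named miR-122, miR-21a, miR-155, miR-146a, miR-34a, miR-29a, miR-29b, miR-29c, miR-223, miR-126a, miR-150 and miR-451a, the 5 brightest miRNAs and up to 4 members per list with the smallest p. The let-7 family members that did not pass and the markers in the closing part were added after their values were seen. The lists were the let-7 family, the miR-17-92 and paralogous clusters, hepatocyte, haematopoietic, endothelial and mesenchymal, epithelial, muscle and neuronal miRNAs, miR-29 and fibrosis-linked miRNAs, inflammation and stress miRNAs, the Dlk1-Dio3, miR-182/miR-96/miR-183 and Sfmbt2 clusters, and GC-rich or rRNA- and tRNA-derived miRNAs. A list name without a letter, such as miR-126, also took the lettered names of the array, such as miR-126a. Genomic positions are from a match of each mature sequence, with U read as T, to the 2202 miRNA transcripts of GENCODE M21 on GRCm38 (Python 3.11.15). All 71 named miRNAs matched, and positions count from 1.

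The procedure was tested on simulated arrays with the levels and spread of the real ones. In 10 simulated T-C cell against control cell comparisons of 476 miRNAs, limma called 86.5% of 20 miRNAs raised 2-fold and 88.0% of 20 lowered 2-fold, 99.5% and 99.0% at 4-fold, and all at 16-fold. Of 356 unchanged miRNAs, 1.26% were called, and 3.78% of calls were false. For a list of 14 members in the same comparison, the permutation test gave an unadjusted p under 0.05 in 5.0% of 500 unshifted lists and 99.8% of lists shifted by 0.4. The simulation draws each miRNA independently, which the real arrays do not do. It also changed far more miRNAs per run than the 37 that passed on the real arrays. More changed miRNAs make the adjusted threshold easier to pass, so the shares called at 2-fold may be too high for these data.

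Alternatives covered normalization (quantile, median centring, none), background (blank-subtracted, no offset, offsets of 16 and 200), the filter (none, all arrays, upper part by mean), robust and array-weighted fits, the replicate number as a block, and each array left out. Figures were drawn with matplotlib 3.10.9.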

Results

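MicroRNA levels were measured on 10 one-colour mouse microarrays, 5 from samples titled T-C cell and 5 from samples titled control cell. The labels place the RNA in liver, name a mouse liver cell culture protocol and give all animals as male. They state a dose of 0.5 mg TN-CF per dish of 100000 T-C cells for 24 hours alongside a control. The source label also differs between the groups (Col-/- against Control Col), so the comparison answers how treated T-C cells differed from control cells, without separating treatment from source. The samples of both groups are described as sle liver. What TN-CF, T-C, Col and sle stand for is not stated in the labels, and the design text writes TB-CF. Nothing in the labels says that the 5 samples of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Each array carried 3968 spots, of which 3784 were miRNA probes at 2 spots per miRNA. Between 189 and 1314 miRNAs were detected per array, 465 ± 186 in T-C cell and 618 ± 410 in control cell samples (SD, n = 5, exact two-sided permutation p = 0.587). The difference was −152 with all arrays and 21.9 without control cell replicate 5, which had the 1314. Before normalization the median log2 intensity was 7.27 ± 0.61 in T-C cell and 7.11 ± 0.65 in control cell arrays (SD, n = 5, exact two-sided permutation p = 0.698). The number of arrays limits the precision of every value below.

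miR-29a-3p, a regulator of collagen and other extracellular matrix genes, had the largest difference of all tested miRNAs. On the scale with 50 added to each intensity it fell 21.9-fold (log2 difference −4.45, 95% interval −4.91 to −3.99), from a log2 level of 12.63 ± 0.15 in control cell to 8.18 ± 0.45 in T-C cell samples (SD, n = 5 each, limma adjusted p = 3.74e-08), and was lower in 5 of 5 T-C cell samples. The size depends on how background is treated, since the log2 difference was −6.96 with blanks subtracted to a floor of 1 and −3.84 with 200 added. Of the let-7 family, which restrains growth-promoting genes such as Hmga2 and the Ras genes, 5 of 14 tested members rose: let-7k 2.11-fold (1.49 to 3.00), let-7e-5p 1.97-fold (1.54 to 2.52), and let-7b-5p, let-7a-5p and let-7d-5p by smaller amounts. miR-150-5p, a lymphocyte miRNA, and miR-133b-5p, a muscle miRNA, also rose, while the other changes were decreases, among them miR-34c-3p, miR-34b-3p, miR-654-3p and miR-7b-3p.

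Of 476 miRNAs tested with limma, 37 passed an adjusted p of 0.05, 7 higher and 30 lower in T-C cell samples, and 29 of the lower ones were lower by at least 2-fold. At an unadjusted p of 0.05, 87 passed. The groups did not overlap for 18 of the tested miRNAs, or 3.78%, where chance gives 0.794%. The split was 14 higher and 33 lower with quantile normalization and 1 higher and 13 lower with median centring. The count at the adjusted threshold changed when single arrays were left out. It was 12 without T-C cell replicate 1, 2 without T-C cell replicate 4 and 3 without control cell replicate 1. Without control cell replicates 2, 3 and 5 in turn it was 1, 1 and 3. In the same order, these fits gave 77, 88, 75, 80, 77 and 69 miRNAs at an unadjusted p of 0.05. The unadjusted counts thus changed far less than the adjusted ones. miR-29a-3p passed the adjusted threshold in each of these fits. It was the single miRNA left without control cell replicate 2 and without control cell replicate 3, and also with all miRNAs on the array tested or, chosen after seeing the data, without both T-C cell replicates 1 and 3. Among the 946 miRNAs in the upper part by mean, more than the 476 of the main test, it and let-7e-5p alone passed.

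**Figure D1:**
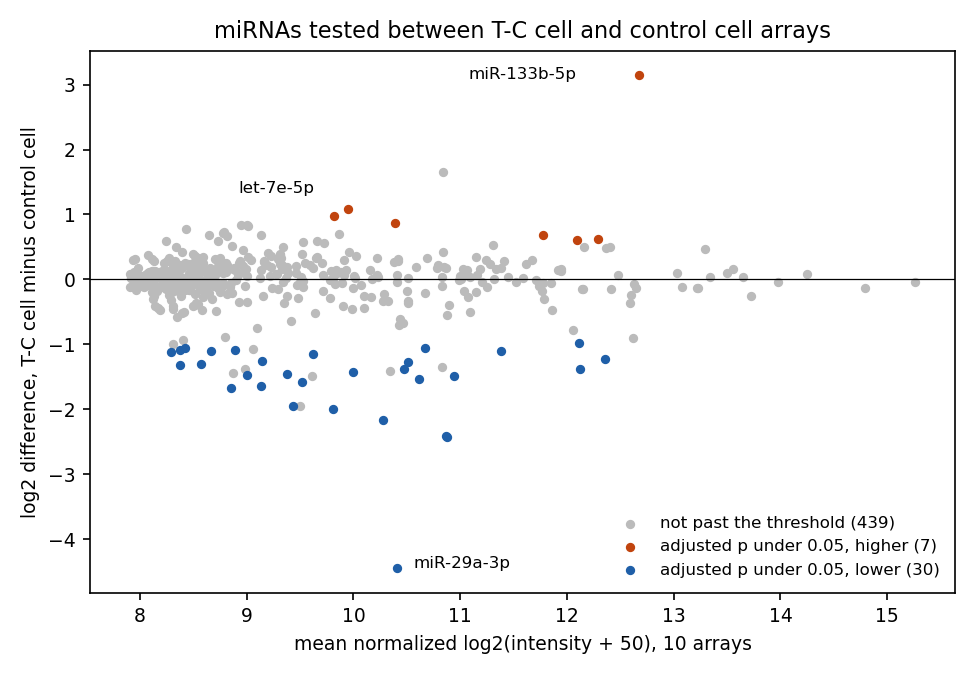
Log2 difference between T-C cell and control cell arrays (vertical axis) against mean normalized log2 intensity over 10 arrays (horizontal axis) for the 476 tested miRNAs, one point each. Red points are the 7 higher and blue points the 30 lower miRNAs at an adjusted p under 0.05, with miR-29a-3p lowest at −4.45 and miR-133b-5p highest at 3.14.

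In the miR-29 family, miR-29a-3p (UAGCACCAUCUGAAAUCGGUUA) had a raw intensity of 264 ± 105 in T-C cell and 6257 ± 898 in control cell arrays (SD, n = 5 each), and on T-C cell replicate 3 it lay below that array's detection limit of 474 and below the mean of its blank spots. Its log2 difference of −4.45 (SE 0.21) is on the scale of log2(intensity + 50), which understates the change of a miRNA close to background. miR-29b-3p had a log2 difference of −0.88 (SE 0.29, limma adjusted p = 0.0932), which did not pass, and miR-29c-3p one of 0.19 (SE 0.34, limma adjusted p = 0.835). The signs of the 3 members held under each scaling tried. Over all alternatives miR-29c-3p ranged from −0.04 to 0.62, while miR-29a-3p and miR-29b-3p stayed negative. miR-29a-3p and miR-29c-3p differ by the substitution C10U, counted from the 5′ end of miR-29a-3p. The raw intensity of miR-29c-3p was 1962 ± 1319 in T-C cell and 1441 ± 256 in control cell arrays (SD, n = 5 each). The miR-29a-3p sequence matched the Mir29a hairpin on chromosome 6 of GRCm38 (31062673 to 31062694, minus strand), outside other annotated genes. miR-29b-3p matched Mir29b-1 beside it (31063025 to 31063047, minus strand) and Mir29b-2 on chromosome 1 (195037091 to 195037113, plus strand). miR-29c-3p matched chromosome 1 as well (195037600 to 195037621, plus strand), and both chromosome 1 sites lay in an exon of the non-coding gene A330023F24Rik. Over the list of miR-29 and fibrosis-linked miRNAs, 1 of 17 tested members fell and 16 did not pass, also when adjusted over the list alone. The list mean differed by −0.39 (exact two-sided permutation p = 0.0159, adjusted p = 0.0688) and the median member by −0.10, and without T-C cell replicate 1 the list mean differed by −0.24. miR-21a-5p, abundant and linked to fibrosis and inflammation, stood at 13.59 ± 0.16 against 13.85 ± 0.14 (SD, n = 5, limma adjusted p = 0.362).

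**Figure D2:**
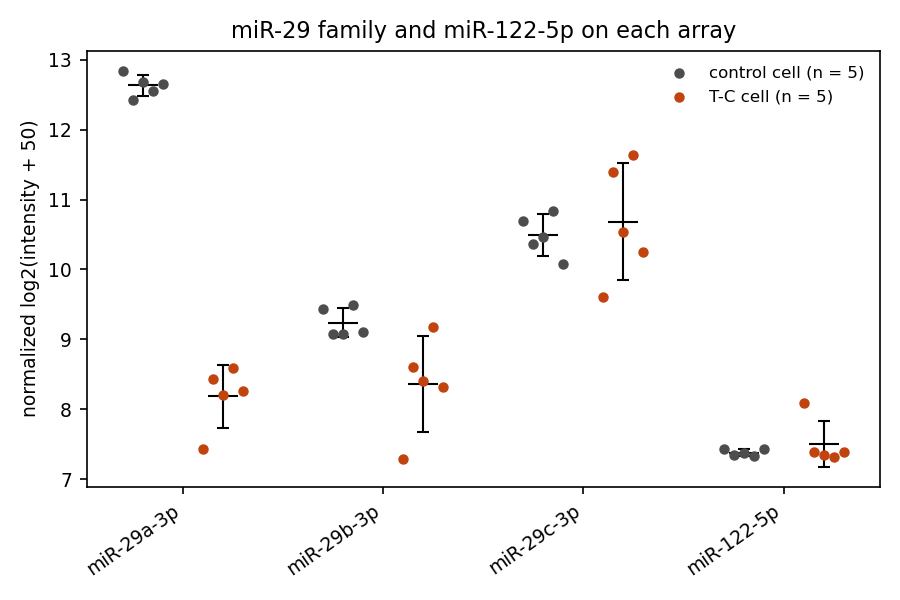
Normalized log2(intensity + 50) of miR-29a-3p, miR-29b-3p, miR-29c-3p and miR-122-5p, with one point per array, black bars for the mean and SD of 5 control cell (grey) and 5 T-C cell (red) arrays. miR-29a-3p averages 8.18 in T-C cell and 12.63 in control cell arrays, while miR-29c-3p overlaps between the groups.

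In the let-7 family, 5 of 14 tested members rose, none fell and 9 did not pass, and 8 rose when adjusted over the list alone. let-7e-5p went from 9.33 ± 0.23 to 10.31 ± 0.17 (SD, n = 5, limma adjusted p = 0.0142) and let-7k from 9.41 ± 0.45 to 10.49 ± 0.29 (limma adjusted p = 0.0391). let-7b-5p, let-7a-5p and let-7d-5p had log2 differences of 0.68, 0.62 and 0.61 (limma adjusted p = 0.0351, 0.0419 and 0.0419). All of these were higher in 5 of 5 T-C cell samples than in any control cell sample. Of those that did not pass, let-7c-5p and let-7f-5p differed by 0.49 each (limma adjusted p = 0.0571 and 0.0974), let-7j by 0.42 and miR-98-5p by 0.37. let-7i-5p differed by 0.23 (SE 0.14) and let-7g-5p by 0.17 (SE 0.15). The 3p arms let-7a-1-3p, let-7b-3p and let-7d-3p differed by −0.02, −0.03 and −0.03. The list mean was higher by 0.43 (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 can give, adjusted p = 0.0688 over 13 lists). With camera at a preset correlation of 0.01 the list passed (adjusted p = 7.99e-07). With the estimated correlation of 0.427 it did not (camera adjusted p = 0.618). Set against that estimate, the p at the preset correlation is too small. Under median centring, and with all miRNAs on the array tested, none of the 5 members that rose passed. Without normalization, or with blanks subtracted to a floor of 1, let-7b-5p, let-7a-5p and let-7d-5p did not pass. The call of let-7e-5p (mmu-let-7e-5p on the array) ended without control cell replicate 2 (limma adjusted p = 0.0615) or control cell replicate 3 (0.0560). Those of let-7k, let-7b-5p, let-7a-5p and let-7d-5p ended without any 1 of T-C cell replicate 4 or control cell replicates 1, 2, 3 and 5, and those of let-7a-5p and let-7d-5p also without T-C cell replicate 1 or 5. The family's members differ by few bases and may share signal on the array, so the size of any single member's change is uncertain. let-7e-5p lies in an intron of Spaca6 (chromosome 17, 17830366 to 17830387, plus strand), let-7k on chromosome 5 (147283257 to 147283275, minus strand), and let-7d-5p on chromosome 13 (48536078 to 48536099, minus strand) in an exon of the non-coding gene 6720427I07Rik.

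**Figure D3:**
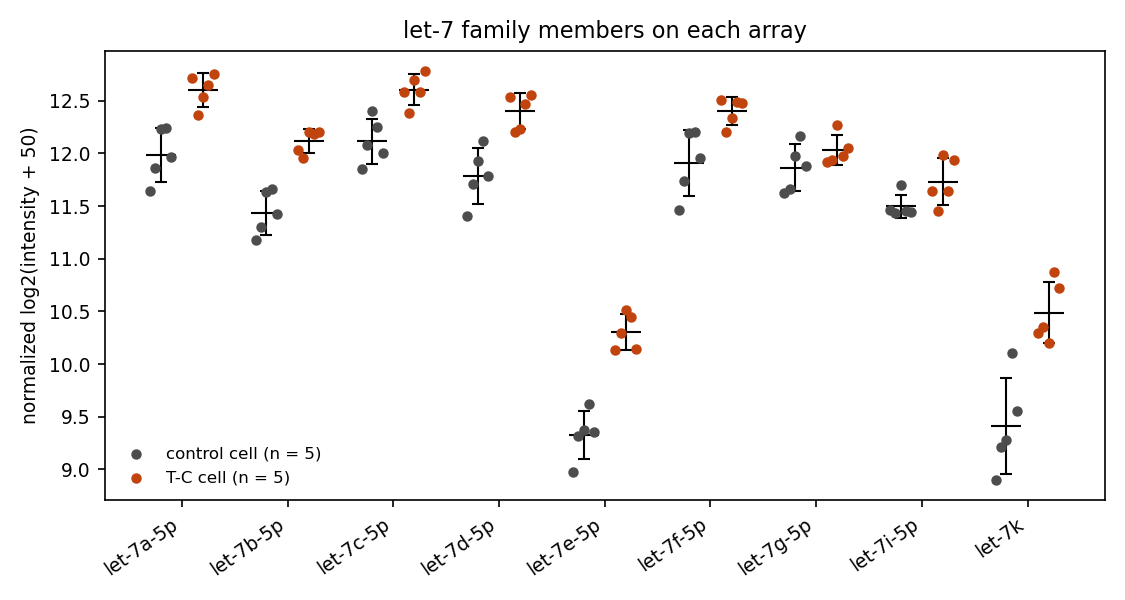
Normalized log2(intensity + 50) of 9 let-7 family members, with one point per array and black bars for the mean and SD of 5 control cell (grey) and 5 T-C cell (red) arrays. let-7e-5p and let-7k have the largest differences between group means, with means of 10.31 and 10.49 in T-C cell against 9.33 and 9.41 in control cell arrays.

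Blood and muscle miRNAs held single members that rose. Of 8 tested haematopoietic miRNAs, miR-150-5p rose by 0.86 (SE 0.23, limma adjusted p = 0.0433), also when adjusted over the list alone, and 7 did not pass, among them miR-342-3p (0.38), miR-142-5p (0.39) and miR-223-3p (0.29). The haematopoietic list mean was higher by 0.31 (exact two-sided permutation p = 0.0397, adjusted p = 0.124). Its camera call at the preset correlation of 0.01 (adjusted p = 0.0421) was lost with the estimated one of 0.186 (adjusted p = 0.618). Of 5 tested muscle miRNAs, miR-133b-5p rose by 3.14 (SE 0.83, limma adjusted p = 0.0419), with levels of 14.25 ± 1.23 against 11.11 ± 1.88 (SD, n = 5) that overlapped between groups. miR-133b-3p, from the other arm of the same hairpin, had a log2 difference of −0.70 (SE 0.22, limma adjusted p = 0.0813) and the near-identical miR-133a-3p one of −0.67 (SE 0.24). Adjusted over the list alone, 1 muscle miRNA was higher and 2 were lower, and the list mean was higher by 0.39 while the median member was −0.06 (exact two-sided permutation p = 0.111, adjusted p = 0.206). The miR-150-5p call ended under median centring, without normalization, and without background correction and offset, the miR-133b-5p call with array weights, and both calls with blanks subtracted to a floor of 1. The miR-150-5p call also ended without any 1 of T-C cell replicates 1, 4 and 5 or control cell replicates 1, 2, 3 and 5, and the miR-133b-5p call without any 1 of T-C cell replicates 1, 2 and 4 or control cell replicates 2, 3, 4 and 5. Without T-C cell replicate 3 or control cell replicate 4, mmu-miR-133a-3p (−0.86 and −0.80) and mmu-miR-133b-3p (−0.84 and −0.85) passed. On chromosome 1, miR-133b-5p matched positions 20682797 to 20682818 (plus strand) in an exon of the lincRNA gene Gm28653.

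Among inflammation and stress miRNAs, miR-34c-3p fell by 1.48 (SE 0.34, limma adjusted p = 0.0400) and miR-34b-3p fell by 1.15 (SE 0.29, limma adjusted p = 0.0419), while 12 of 14 members did not pass, the same counts as when adjusted over the list alone. miR-34a-5p, the 5p arm of a relative, had a log2 difference of −0.32, miR-155-5p one of 0.13 and miR-146a-5p one of −0.18, none of which passed. The list mean was −0.24 (exact two-sided permutation p = 0.0476, adjusted p = 0.124). Without T-C cell replicate 1, where the list mean was 8.96, it was −0.09, and mmu-miR-34a-5p was −0.05. Of 8 neuronal miRNAs, miR-7b-3p fell by 1.09 (SE 0.24, limma adjusted p = 0.0400), also when adjusted over the list alone, and 7 did not pass (list mean −0.19, exact two-sided permutation p = 0.0635, adjusted p = 0.138). In the Sfmbt2 cluster, whose copies are near-identical and may share signal, miR-467a-3p and miR-467d-3p fell by 1.10 and 0.98, and 51 of 53 members did not pass, while 0 passed when adjusted over the list alone. The Sfmbt2 list mean differed by 0.05 (exact two-sided permutation p = 0.611, adjusted p = 0.662) and by −0.03 without T-C cell replicate 1. Each of the 5 decreases in this paragraph lost its call under median centring, with blanks subtracted to a floor of 1, and without any 1 of T-C cell replicate 4 or control cell replicates 1, 2, 3 and 5. Those of miR-467a-3p and miR-467d-3p also ended without normalization, and that of miR-467d-3p without background correction and offset. Without T-C cell replicate 1 that of miR-7b-3p alone held, without T-C cell replicate 3 those of miR-34b-3p and miR-467d-3p ended, and without T-C cell replicate 2 that of miR-467d-3p.

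The groups did not overlap for 8 of the 30 miRNAs that fell. Those in none of the lists were miR-1894-5p (−1.67, SE 0.44), miR-654-3p (−1.59, SE 0.31), miR-3968 (−1.46, SE 0.35), miR-7056-3p (−1.37, SE 0.28), miR-6917-3p (−1.28, SE 0.27) and miR-7674-3p (−1.10, SE 0.26), with limma adjusted p from 0.0351 to 0.0419. These calls ended with blanks subtracted to a floor of 1 and, except that of miR-1894-5p, under median centring. They ended without any 1 of T-C cell replicate 4 or control cell replicates 1, 2 and 3, and, except that of miR-654-3p, without control cell replicate 5. Those of miR-1894-5p and miR-7674-3p ended also without T-C cell replicate 1, and that of miR-1894-5p without T-C cell replicate 2. Several of these lie in genes for proteins: miR-7056-3p in an intron of Ptpn5 (chromosome 7, 47083166 to 47083187, minus strand), miR-6917-3p in an intron of Erbb3 (chromosome 10, 128584437 to 128584458, minus strand) and miR-1894-5p in an exon of Ppp1r10 (chromosome 17, 35917899 to 35917920, plus strand). miR-654-3p lies on chromosome 12 (109723270 to 109723291, plus strand), between miR-667-3p (109720061 to 109720083) and miR-376b-3p (109723508 to 109723528) of the Dlk1-Dio3 cluster, whose list did not name it. Of the 30 miRNAs that fell, 28 hold the sequence ACC, against 96 of the 446 other tested miRNAs, a difference noticed in these data. T-C cell replicate 1 stood apart from the other arrays on the first principal component (50.4% of the variance) at −15.8, with the other T-C cell arrays between −5.10 and −1.34 and the control cell arrays between 1.63 and 8.05. It also had the lowest levels of miR-29a-3p, miR-3968 and miR-1894-5p among the T-C cell arrays.

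For the other cell types the lists gave these values. Endothelial and mesenchymal miRNAs had a list mean higher by 0.24 (exact two-sided permutation p = 0.0159, adjusted p = 0.0688), with 13 of 13 members not passing, miR-10b-5p at 0.70, miR-100-5p at 0.58 and miR-126a-3p at −0.01. For epithelial miRNAs the list mean was −0.15 (exact two-sided permutation p = 0.294, adjusted p = 0.347), with 10 of 10 members not passing, miR-375-3p at −0.51 and miR-200a-3p at −0.37, and without T-C cell replicate 1 the list mean was −0.05. Hepatocyte miRNAs had a list mean of 0.21 (exact two-sided permutation p = 0.135, adjusted p = 0.219), with 8 of 8 members not passing. On control cell replicate 1, which had the lowest list mean of all arrays (10.12), the 2 spots of its member miR-192-5p had raw intensities of 167 and 15049. Over the alternatives the difference of the hepatocyte list mean ranged from 0.12 to 0.45 without passing. miR-122-5p, the dominant miRNA of hepatocytes, was not tested, because it exceeded the detection limit on 1 of 10 arrays. The miR-17-92 and paralogous clusters (0.11, exact two-sided permutation p = 0.286, adjusted p = 0.347, 12 members), the Dlk1-Dio3 cluster as listed, without miR-654-3p (−0.07, exact p = 0.214, adjusted p = 0.310, 16 members) and the GC-rich or rRNA- and tRNA-derived miRNAs (0.00, exact p = 0.992, adjusted p = 0.992, 17 members) had no listed member that passed. In the hepatocyte, endothelial and mesenchymal, epithelial, miR-17-92, Dlk1-Dio3 and GC-rich lists, 0 members passed when adjusted over the list alone. The miR-182/miR-96/miR-183 cluster had 2 tested members, miR-182-5p at −0.41 and miR-183-5p at −0.10, neither passing when adjusted over the list alone, too few for a list test. By the permutation test 0 of 13 lists passed after adjustment and 5 had an unadjusted p under 0.05. At the smallest possible p, 1 list alone gives an adjusted p of 0.103 and 2 lists give 0.0516, so fewer than 3 lists could not pass together. With camera, 2 lists passed at the preset correlation and 0 with an estimated correlation (adjusted p = 0.618 for both). The brightest miRNAs were miR-341-5p, miR-709, miR-145a-5p, miR-143-3p and miR-21a-5p, with mean log2 levels of 15.26, 14.79, 14.25, 13.97 and 13.72 over all arrays, and none of them passed.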

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

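The tests in this part were set before the results were seen, except the look at the spots of miR-192-5p and at miR-194-5p, which was chosen after. In each group of 5 arrays, the highest or lowest value was set against the spread of the others, and 16 of 172 such groups held a value far from the rest, where chance gives about 5 percent. T-C cell replicate 1 held 5 of these values, control cell replicate 4 held 4 and control cell replicate 5 held 4. All values are normalized log2 intensities.

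On T-C cell replicate 1, miR-34a-5p stood at 7.15 against 8.23 to 8.48 on the other T-C cell arrays, miR-3968 at 7.41 against 8.77 to 9.11, miR-138-1-3p at 7.54 against 7.99 to 8.08, and the mean of the inflammation and stress list at 8.96 against 9.58 to 9.74. On the same array miR-122-5p stood high at 8.10 against 7.31 to 7.39. T-C cell replicate 3 had a high miR-125b-5p, 13.16 against 12.45 to 12.62.

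On control cell replicate 4, miR-133a-3p stood at 10.26 against 10.83 to 11.03 on the other control cell arrays, miR-133b-3p at 10.15 against 10.87 to 11.02, miR-146a-5p at 9.92 against 10.63 to 10.87 and miR-467d-3p at 11.72 against 12.72 to 12.88. On control cell replicate 5, miR-138-1-3p stood at 9.73 against 7.95 to 8.06, miR-34b-3p at 11.10 against 9.83 to 10.15, miR-142-3p at 8.47 against 7.97 to 8.06 and miR-194-2-3p at 7.87 against 8.05 to 8.11. On control cell replicate 2, miR-378d stood at 9.71 against 10.29 to 10.38. On control cell replicate 1, miR-192-5p stood at 10.61 against 13.47 to 14.13, where its 2 spots had raw intensities of 167 and 15049, while miR-194-5p on that array stood at 13.51 against a mean of 13.43 on the other 4. None of the 26 kinds of control spot was higher, or lower, on every T-C cell array than on every control cell array. The 2 with an unadjusted exact two-sided permutation p under 0.05 were calibration spots lower in T-C cell arrays, by raw log2 differences of −0.47 (exact p = 0.0159, adjusted p = 0.413) and −0.38 (exact p = 0.0476, adjusted p = 0.438).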

How the results depend on the processing

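The alternatives were chosen before the data were examined, except 4: both T-C cell replicates 1 and 3 left out, blanks subtracted before adding 50, the brighter of the 2 spots, and list names exactly as written. miR-29a-3p passed under each of the 25 alternatives that tested it (log2 difference −6.96 to −3.84, limma adjusted p 9.08e-10 to 0.0111), and was not tested among miRNAs detected on all arrays. Against 37 changed miRNAs (7 higher, 30 lower), median centring gave 14 (1 and 13), of which 13 were among the 37. Blank subtraction with a floor of 1 gave 3 (2 and 1). The 946 miRNAs in the upper part by mean, more than the 476 of the main test, gave 2 (1 and 1). Quantile normalization gave 14 higher, no normalization 3 higher with a median log2 difference of 0.14 over all tested miRNAs against 0.02, and blanks subtracted before adding 50 gave 13 higher. Testing all miRNAs on the array gave 1 (0 and 1), and the 176 detected on all arrays 18 (9 and 9), where each of the 16 original calls still tested passed again. Without both T-C cell replicates 1 and 3 the count was 1 (0 and 1). Leaving out each array in turn gave 1 to 44 changed, 0 to 8 higher and 1 to 36 lower. With the replicate number as a block (replicate block) 22 changed, 4 higher and 18 lower. Same-numbered arrays correlated at −0.11, −0.20, 0.06, −0.11 and 0.26, and 1 of 5 correlated best with its own number. These values do not settle whether same-numbered samples belong together. Except where fewer or more miRNAs or arrays entered, the cause was not tested. Each of the 37 kept its direction wherever it was tested. Of 19 named miRNAs past the threshold, 282 of 486 values under alternatives stayed past it, 204 did not and 0 turned direction. let-7e-5p passed under 21 of 26 alternatives and let-7k under 17. Of 51 named miRNAs not past it, 15 of 1280 values passed and 42 turned sign without passing. With camera 2 lists passed at the preset correlation and 0 with an estimated correlation. The permutation test gave 0 lists under each alternative, as with all arrays, where fewer than 3 of 13 lists could not pass together. With arrays left out, more lists would have had to pass together, and with the replicate number as a block no list could pass. These counts of 0 therefore say little. Detected miRNAs (difference −227 to 21.9) and raw intensity (−0.08 to 1.02) passed under none, where the block of 5 pairs could not pass. The median of 2 spots equals their mean, and all arrays carry the same probes, so these alternatives were not run. Signal over background limits the weak miRNAs: uneven blanks on T-C cell replicate 3 set its limit at 474, with 189 miRNAs detected.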

Other observations

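The tests in this part on single spots of miR-29a-3p, on miR-29c-3p and miR-29b-3p, on the sequence ACC, on the slope of the calibration spots and on miR-122-5p were chosen only after the results were seen, while the splits of the arrays, the correlation with the calibration spots and T-C cell replicate 1 were chosen before.

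The arrays carried strong signal for markers of epithelium and of smooth muscle or mesenchyme in both groups. Probes differ in brightness, so ranks across miRNAs do not measure abundance. Among the top 5 percent of miRNAs by mean level (94 miRNAs) were miR-200b-3p (log2 level 13.08), miR-429-3p (12.60), miR-200a-3p (12.59), miR-200c-3p (11.95), miR-375-3p (11.09) and miR-141-3p (10.67), and also miR-145a-5p (14.25), miR-143-3p (13.97), miR-145b (13.56), miR-125b-5p (12.40), miR-126a-3p (11.71) and miR-199a-3p (11.38). From the hepatocyte list, miR-194-5p (13.50), miR-192-5p (13.29), miR-215-5p (11.31) and miR-148a-3p (11.07) were there too, the first 3 of which intestinal epithelium also expresses.

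miR-122-5p was close to blank spots although the labels name liver, at percentile 5.13 of all miRNAs by mean level. A probe that gives no signal remains open, since both spots exceeded the detection limit on 0 arrays and 1 array exceeded it by the mean of the spots. RNA with few hepatocytes cannot be told apart from this, since the low level is what raised the question, ranks across probes do not decide it, and no sample known to hold hepatocytes was measured here.

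The loss of miR-29a-3p was seen on 10 of 10 T-C cell spots, each below the lowest control cell spot, which argues against a defect of single spots. The lower end of the 95% interval for miR-29c-3p, the closest sequence tested, was −0.56, which argues against a signal loss of that size shared by similar probes. Loss of the chromosome 6 locus, which also holds Mir29b-1, remains a hypothesis. miR-29b-3p differed by −0.88, inside the middle 90 percent of the other tested miRNAs that hold ACC (−1.67 to 0.53). That comparison decides little, since the set includes the other lower miRNAs with ACC and miR-29b-3p lay close to background in T-C cell arrays. Loss of the locus cannot be told apart from the other decreases, also because miR-29b-3p comes from chromosome 1 as well. The treatment and the source of the cells, which differ together between the groups, stay open and untested.

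Of 100 splits of the 10 arrays into 5 and 5, 1 gave as many changed miRNAs as the real one. That split was the real one itself, with 37, and the highest other gave 9. This argues against a random division of the arrays as the source of the count, although not all possible splits were drawn. The splits do not address a batch that follows the array numbers. One that changes both below and above the control cell numbers cannot be told apart from the group. A sequence pattern was noticed in the calls, so no test of it on them is given: 28 of the 30 lower miRNAs hold ACC, against 21.5% of the other tested ones, and the median A or C content was 69.8% in the lower miRNAs, 22.7% in the 7 higher ones, 5 of them let-7 members of similar sequence, and 47.6% in those that did not pass. Without T-C cell replicate 1 the lower calls dropped from 30 to 9. Of these 9, 8 hold ACC, a count made after the data were seen. These 9 calls, made without that array, argue against it as a single cause of the pattern. The median log2 difference of the 29 lower miRNAs other than miR-29a-3p was −1.15 without that array and −1.37 with it. That comparison decides little, since the 29 were chosen as lower with all arrays. A signal that depends on sequence cannot be told apart from the groups: among miRNAs that did not pass, the median difference of those with ACC minus that of those without was −0.0874 (permutation p = 0.00596), but decreases just short of the threshold would give this whatever their cause. Hybridization strength as read by the calibration spots differed by −0.24 on the log2 scale between groups (exact permutation p = 0.317), from intensities before normalization. To give the −1.45 of those 29 miRNAs, taken after normalization, it would need a slope of 6.17, and the slope within groups was −0.28. Taken as known, the needed slope is argued against (exact permutation p of the needed slope = 0.000556). This does not decide hybridization strength as the whole cause, since that slope rests on an uncertain difference and on miRNAs chosen for being lower. Normalization between arrays may also have removed such strength from the miRNA levels already. A part in the pattern cannot be told apart either, as the correlation within groups over 10 arrays was −0.185 (exact permutation p = 0.644). The Spearman value was −0.20 (exact permutation p = 0.633), and r was −0.218 without the 2 arrays farthest from the median. The treatment and the source of the cells stay open and untested.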
